A study of Mus musculus with 48 samples.

How the data were processed

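The series holds 48 arrays of total RNA from primary mouse embryonic fibroblasts of 2 CREB genotypes. Each genotype had 4 treatments, in batches A and B with 3 arrays per group and batch. Per the labels, cells were serum starved for 16 h. They were then treated with forskolin for 90 min, exposed to 20 Gy of ionizing radiation and collected at 120 min, or given 20 Gy 30 min before forskolin. For cells given both, neither the length of forskolin treatment nor the time of collection is stated. Per the file headers, the deposited array files hold intensity values from Agilent Feature Extraction 10.7.3.1 (protocol GE1_107_Sep09, array design 028005). Their processed signals are background subtracted and detrended within the array and not normalized between arrays. Per the file headers the same files hold flags of the software (other units, 0 or 1) for outliers and signals well above background, and probe positions on mm9. The deposited values of the authors cover 50712 probes and were read as log2 from their range. How the authors normalized them is not stated. Their column medians lie between 6.03 and 6.39 and their rank correlation with the processed signal of the same array between 0.988 and 0.996, so the direction is known and the method of centring is not.

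Each array has 62976 spots, of which 59305 are not controls, for 55681 probes. Of these 27509 matched a RefSeq transcript by accession and took its symbol (2017 of them a new one), and 22425 are named only by an accession. Spots that the software marked as outliers were left out and replicate spots of a probe averaged. The processed signal was taken as log2 and each array's 75th percentile was subtracted. Probes well above background on at least 3 of the 6 arrays of at least 1 group were kept (46001). Each gene was represented by the kept probe with the highest mean over all arrays, among those with a value on at least 40 arrays, a minimum not fixed beforehand. This left 30290 genes, 9348 of them known only by an accession or locus, and 4150 with a spot left out on at least 1 array.

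Limma 3.58.1 in R 4.3.3 (data.table version 1.17.8) fitted the 8 groups with batch as a fixed term. The number in the sample title, which each of 24 numbers gives to 1 array of batch A and 1 of batch B, was a random block (consensus correlation 0.0576). Tests are two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all genes. The labels do not say whether arrays came from separate cultures or whether arrays with 1 title number share RNA, so p-values measure only the spread between these samples. There are 18 comparisons: 8 of treatments within a genotype, 4 of genotypes within a treatment and 6 interactions. The word replicate with a number means a title number, so leaving 1 out removes 1 array of each batch. The 3 S111A Fsk_IR arrays of batch A all carry the replicate label A1, and A1, A2 and A3 were given to them in the order of their title numbers, which also enters the replicate block.

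The comparisons, 22 gene lists, the rule for named genes and most of the other ways to process the arrays were fixed before the data were examined. The lists cover cAMP/CREB early targets, p53 targets, growth factor feedback and MAPK genes, inflammatory genes, the circadian clock, CREB family and cAMP enzymes, and gluconeogenesis and PGC-1alpha. They also cover oxidative phosphorylation, cholesterol synthesis, extracellular matrix, SRF and YAP targets, G2/M, S phase, DNA damage signalling, ER stress, 6 sets of markers of other cell types and embryo sex genes. Lists were tested with limma's camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, adjusted over 396 tests. Camera compares a list with other genes and takes no block for the title number, and values left out were filled with fitted values for these tests. The rule named up to 10 genes each way with the largest change in the 8 treatment comparisons and genotype under control, and up to 3 in the others. They had adjusted p under 0.05, signal above background on every array of a group and the same sign in both batches. Up to 4 members of each list with the largest change were named too, and Creb1 and Crem in any case. Features known only by an accession or locus were skipped. List scores are means over members, batch centred and averaged over each title number, compared by two-sided exact permutation tests.

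The alternatives were quantile normalization, normexp background correction with an offset of 50, the authors' values, no filter, a stricter filter, the mean over probes, independent arrays, averaged arrays, no batch term, each batch alone, a replicate block, a fit to the compared groups alone, an intensity trend, and leaving out each title number. A block for the slide was foreseen where files gave the slide. Its fixed and random forms, leaving out slide 3, array weights and the genotype average over treatments were chosen after seeing the data. In simulated data with the variances of the fit and changes given to 50 genes per size, limma recovered 6%, 36%, 64% and 92% of log2 changes of 0.5, 1, 2 and 4. It called 5 other genes. The simulated noise had no slide or array-wide structure, unlike these arrays (consensus correlation within a slide 0.354). These numbers therefore do not give the rate of false or missed calls on the real arrays.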

Results

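RNA from primary mouse embryonic fibroblasts was measured on 48 single-color (Cy3) whole genome arrays. The cells carried either wild type CREB (WT) or the S111A allele, in which alanine replaces a serine of this cAMP-responsive transcription factor, so that the residue cannot be phosphorylated. Serum-starved cells of each genotype were left as controls, treated with forskolin (Fsk, an activator of adenylyl cyclase), exposed to ionizing radiation (IR), or irradiated and then given forskolin (Fsk_IR). Each of the 8 groups held 6 arrays, 3 in batch A and 3 in batch B. The arrays carried between 12961 and 52552 probes well above background. Slide 3, with 2 WT control arrays and 2 S111A Fsk_IR arrays of batch A, had negative control signals of 612.6 to 1180.8 against 22.2 to 90.9 on the other 7 slides. Results against these groups are also given with the slide as a block and without slide 3. WT control array B2, on slide 4, had 7015 spots marked as outliers, against 95 to 597 on the other arrays. It stays in those fits and in batch B, and slide 4 is among the slides counted for treated against control WT cells.

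**Figure D1:**
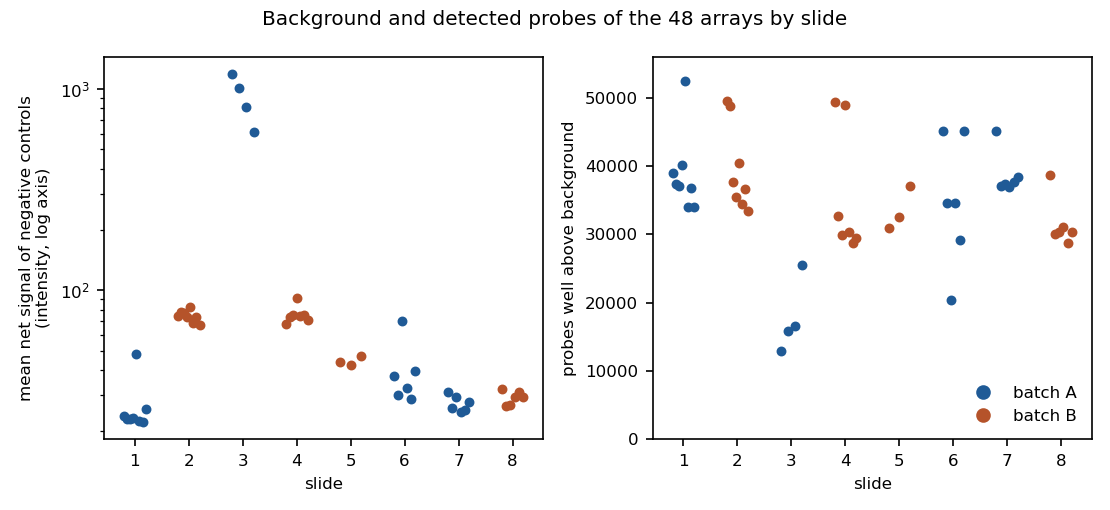
Mean net signal of the negative controls (left, intensity on a log axis) and number of probes well above background (right) for each of the 48 arrays, by slide. Each point is 1 array, and the 4 arrays of slide 3 had the highest negative control signals, 612.6 to 1180.8.

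Changes are relative to each array's 75th percentile, and this scaling sets where 0 lies. The median log2 change of all genes after forskolin in WT cells was -0.12 with it, 0.13 after quantile normalization, -0.12 with normexp and 0.08 in the deposited value table. It was -0.25, 0.13, -0.18 and 0.10 after radiation and -0.17, 0.10, -0.07 and 0.07 after both treatments in WT cells. The 4 values were -0.13, -0.01, -0.08 and -0.02 after forskolin in S111A cells. For S111A against WT it was -0.10, 0.11, -0.08 and 0.08 under control, -0.13, 0.00, -0.07 and 0.00 with forskolin and 0.10, -0.02, 0.00 and -0.03 with radiation. For both treatments against forskolin in S111A cells it was 0.04, -0.07, 0.10 and -0.06.

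The first comparison asks which genes respond to a rise of cAMP in WT cells. Nr4a2, an orphan nuclear receptor and classical CREB target (chromosome 2, probe 56960699 to 56960758 on mm9), rose by 6.02 ± 0.36 on the log2 scale (SE, 6 arrays against 6; 65.1-fold; adjusted p = 4.8e-16). The chemokine gene Cxcl1 rose by 5.94 ± 0.34 (adjusted p = 2.27e-16), the cytokine gene Il6 by 5.81 ± 0.59, Rgs2, a regulator of G protein signalling, by 4.95 ± 0.28, and Fos, a subunit of the AP-1 transcription factor, by 4.67 ± 0.53. C2cd4b (5.34 ± 0.70) and Rasd1 (4.31 ± 0.61) were above background on 2 and 3 of the 6 control arrays and on all 6 treated arrays. Has1, a hyaluronan synthase, rose by 4.37 ± 0.45, the potassium channel subunit Kcne4 by 4.30 ± 0.27 and Ier3 by 4.23 ± 0.40. The 10 genes were higher on each of the 3 slides that held both groups. Within batches A and B the changes were 6.30 and 5.75 for Nr4a2, 6.66 and 5.22 for Cxcl1 and 4.17 and 7.46 for Il6.

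Among lower genes, Txnip, an inhibitor of thioredoxin and of glucose uptake, fell by 1.84 ± 0.26 on the log2 scale (SE; adjusted p = 7.32e-06). The zinc finger genes Zfp273 and Zfp455 changed by -1.87 ± 0.33 and -1.82 ± 0.29, and BB166591, a transcript without a named product, by -2.51 ± 0.41. These 4 were lower on each of 3 slides and passed with the slide as a block. The other 6 named genes, 9130020K20Rik, Sap25, L1td1, BB163080, Lin28b and BC023969, had changes of -1.99 to -1.81, and with the slide as a block their adjusted p lay between 0.103 and 0.39, so those calls ended.

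**Figure D2:**
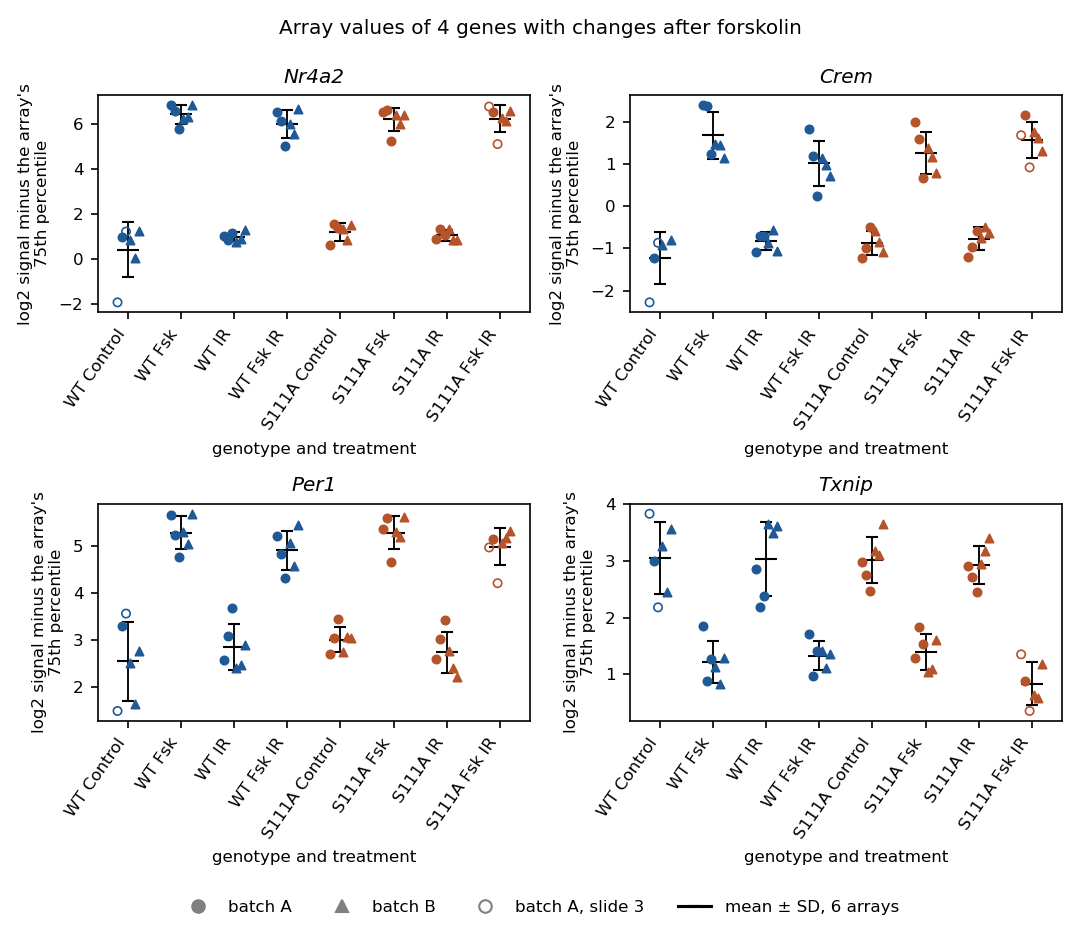
Log2 signal of Nr4a2, Crem, Per1 and Txnip relative to each array's 75th percentile (vertical axis) in the 8 groups of 6 arrays (horizontal axis). Circles are batch A, triangles batch B, open circles slide 3, and bars the mean ± SD; the forskolin-treated groups lie above the others for Nr4a2, Crem and Per1 and below them for Txnip.

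Of the 36 measured cAMP/CREB early targets, 27 rose, 0 fell and 9 did not pass in WT cells, with a median change of 2.20; adjusted over the list alone, 32 were higher and 1 was lower. The largest changes were those of Nr4a2, Rgs2, Fos and Areg, an EGF receptor ligand (4.13 ± 0.37, SE). This list passed limma's camera test (adjusted p = 1.73e-68) and also did so with an estimated correlation between genes (adjusted p = 6.21e-06). Among 24 growth factor feedback and MAPK genes, 9 rose (14 adjusted over the list alone), led by Ier3, Areg, the angiogenic factor Vegfa (2.51 ± 0.32) and Phlda1 (2.21 ± 0.25). The call held with an estimated correlation (adjusted p = 0.00529). Of 25 inflammatory and NF-kB genes, Cxcl1 and Il6 rose (9 adjusted over the list alone), while Cxcl5 (2.11 ± 0.68) and Cxcl2 (1.94 ± 0.66; above background on 1 of 6 control arrays) did not pass. Without slide 3 Cxcl2 passed (3.13, adjusted p = 0.00169). The call of this list was lost in WT cells, with adjusted p = 0.107 with an estimated correlation. In the circadian clock list 4 of 21 genes rose (4 higher and 1 lower adjusted over the list alone): the repressor Nfil3 by 2.99 ± 0.36, the clock genes Per1 by 2.75 ± 0.28 and Bhlhe40 by 2.13 ± 0.28 among them (adjusted p = 0.421 with an estimated correlation). Of 31 genes for CREB family members, coactivators and cAMP enzymes, 2 rose (4 adjusted over the list alone; adjusted p = 0.636 with an estimated correlation): Crem, whose products include a repressor of CREB targets, by 2.91 ± 0.28 and the cAMP phosphodiesterase Pde4b by 1.59 ± 0.23. Each of these called genes was higher on every slide with a value for both groups (3, and 2 for Crem).

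Of 35 p53 targets 4 rose in WT cells, namely the antiproliferative gene Btg2 (2.66 ± 0.29, SE), the kinase Plk3 (2.03 ± 0.33), the BH3-only gene Pmaip1 (1.74 ± 0.37) and the stress cytokine Gdf15 (1.68 ± 0.30), each on 3 of 3 slides. Adjusted over the list alone, 12 p53 targets were higher and 2 lower, and the list had adjusted p = 0.708 with an estimated correlation; Pmaip1 had adjusted p = 0.0822 with the slide as a block. Of 19 ER stress, ATF4 and heat shock genes, 2 rose (4 adjusted over the list alone; adjusted p = 0.708 with an estimated correlation), Ppp1r15a, a phosphatase subunit, by 1.38 ± 0.32 and the chaperone Hsph1 by 0.76 ± 0.19, and neither passed with the slide as a block (adjusted p = 0.106 and 0.0996). Of 24 matrix genes only Has2, a hyaluronan synthase, rose (2.43 ± 0.40), and of 25 SRF and YAP targets only Ier3. Both lists passed camera with medians of 0.75 and 1.10, and both had adjusted p = 0.708 with an estimated correlation. The matrix median was 1.33 in batch A, 0.34 in batch B and 0.11 without slide 3, and that of SRF and YAP targets 1.78, 0.43 and 0.46. The 27 genes for G2/M and mitosis, the 27 for S phase and the 26 for DNA damage signalling and repair held no called member and had camera adjusted p of 0.116, 0.143 and 0.297.

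In all, 599 of 30290 genes had a limma adjusted p under 0.05 in WT cells after forskolin, 362 higher and 237 lower, with 5487 at an unadjusted p under 0.05; 239 of the higher and 173 of the lower genes differed at least 2-fold. With the slide as a block 402 genes were called (254 higher, 148 lower) and without slide 3 there were 577 (446 higher, 131 lower), and 288 genes were called in all 3 fits. The split also moved with scaling: 482 of 593 genes were higher after quantile normalization, 1649 of 1974 with normexp background correction, and 478 of 617 in the deposited value table. Within batch A the count was 230 (79 higher, 151 lower) and within batch B 313 (268 higher, 45 lower). A fit to the 2 compared groups alone called 63 (59 higher, 4 lower). Single replicates moved the count, which was 2031, 341 and 4035 without control replicate 1, 2 or 3, and 390, 264 and 358 without Fsk replicate 1, 2 or 3.

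The same comparison in S111A cells asks whether the response to cAMP needs the serine. Forskolin raised many of the genes named above. Il6 rose by 6.26 ± 0.59 on the log2 scale (SE, 6 arrays against 6), Cxcl1 by 5.96 ± 0.34 (adjusted p = 3.89e-16), Nr4a2 by 5.01 ± 0.36 (adjusted p = 2.35e-13), Rgs2 by 4.67 ± 0.28, Has1 by 4.34 ± 0.45 and Fos by 4.23 ± 0.53. C2cd4b (5.37 ± 0.70), Rasd1 (5.09 ± 0.61) and Scrt1, a zinc finger repressor of neural genes (4.86 ± 0.42), were above background on 2 or 3 of the 6 control arrays. Nr4a3, an orphan nuclear receptor, was above background on 0 of 6 control and 6 of 6 treated arrays and rose at least 7.43-fold, a bound taken against the dimmest probe called above background on each control array. These 10 genes were higher on each of the 5 slides that held both groups.

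Of the 36 cAMP/CREB early targets 23 rose in S111A cells (29 adjusted over the list alone; median 1.78; adjusted p = 8.85e-09 with an estimated correlation). Of the growth factor and MAPK genes 5 of 24 rose (10 adjusted over the list alone; adjusted p = 0.000151 with an estimated correlation), among them Areg (4.11 ± 0.37, SE), Ier3 (3.11 ± 0.40), the MAPK phosphatase Dusp5 (2.18 ± 0.34) and Phlda1 (1.94 ± 0.25). Of the inflammatory genes 5 of 25 rose (6 adjusted over the list alone; adjusted p = 0.000293 with an estimated correlation), including Cxcl2 (3.86 ± 0.66; above background on 1 of 6 control arrays) and Cxcl5 (2.77 ± 0.68). The clock genes Per1 (2.28 ± 0.28), Nfil3 (2.12 ± 0.36) and Bhlhe40 (1.49 ± 0.28) rose (3 of 21; 4 adjusted over the list alone; adjusted p = 0.0633 with an estimated correlation). So did Crem (2.14 ± 0.27) and Pde4b (1.46 ± 0.23) of the CREB family list (2 of 31; 3 adjusted over the list alone; adjusted p = 0.382 with an estimated correlation). The p53 targets Btg2 (2.59 ± 0.29), Gdf15 (1.5 ± 0.30) and Plk3 (1.44 ± 0.33) rose, 3 of 35 (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.708 with an estimated correlation). Each was higher on 5 of 5 slides.

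Among the lower genes of S111A cells, Phxr4 (-2.49 ± 0.60, SE), 5930422O12Rik (-2.29 ± 0.43) and Scai, a suppressor of cell invasion (-2.05 ± 0.52), were above background on 6 of 6 control arrays and on 1 of 6 treated arrays, and Gnrh1 (-2.40 ± 0.54) likewise but lower on 3 of 4 slides. Zfp273 changed by -1.70 ± 0.33 (adjusted p = 0.00197), and BB166591, 9930012K11Rik, D330022H12Rik, 9130020K20Rik and AA386476 by -1.95 to -1.77; these were lower on 5 of 5 slides. Limma called 216 genes, 152 higher and 64 lower (1677 at an unadjusted p under 0.05), against 386 with the slide as a block (225 higher, 161 lower). There were 478 without slide 3 (273 higher, 205 lower). Neither group has an array on slide 3, so that rise comes from the spread pooled over all groups. Quantile normalization gave 142 higher and 14 lower genes and the values deposited by the authors 165 and 23. The count was 140 without S111A control replicate 1, 140 without control replicate 2 and 138 without Fsk replicate 2, and it was 32 within batch A and 221 within batch B.

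The responses to forskolin of the genotypes overlapped. Of 362 genes higher in WT cells and 152 higher in S111A cells, 137 were called in both, against 1.8 if the calls were independent, and 56 lower genes were shared against 0.5. Of the 622 genes called in either genotype, 615 had the same sign in both (98.9%). For genes called in both the median ratio of the S111A to the WT change was 0.92. Over all genes called higher in WT cells the median change was 1.25 in WT and 0.86 in S111A cells. These genes were chosen by their calls in WT cells, so the smaller S111A median does not by itself show a weaker response. Over all genes the changes correlated with r = 0.52. The interaction of genotype and forskolin called 0 genes with limma (smallest adjusted p = 1), with 364 at an unadjusted p under 0.05. The interaction was -1.02 ± 0.51 on the log2 scale (SE) for Nr4a2, -0.77 ± 0.38 for Crem, -1.36 ± 0.71 for the prostaglandin synthase Ptgs2, -1.19 ± 0.65 for Klf4 and -0.94 ± 0.45 for Gadd45b, none past the threshold (adjusted p = 1 for each). Without slide 3 it was -0.64 for Nr4a2, -0.73 for Ptgs2, -0.46 for Klf4 and -0.50 for Gadd45b. The cAMP/CREB list had a median interaction of -0.46 and passed camera (adjusted p = 0.00151), but not with an estimated correlation (adjusted p = 0.738) or with the slide as a block (adjusted p = 0.873). The mean score of the list, per title number and batch centred, went from -1.20 ± 0.60 to 1.17 ± 0.05 (SD, n = 3) in WT cells. In S111A cells it went from -1.01 ± 0.19 to 0.97 ± 0.11. Each two-sided exact permutation p was 0.1, the smallest that 20 arrangements allow (adjusted p = 0.218 over 24 score comparisons).

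**Figure D3:**
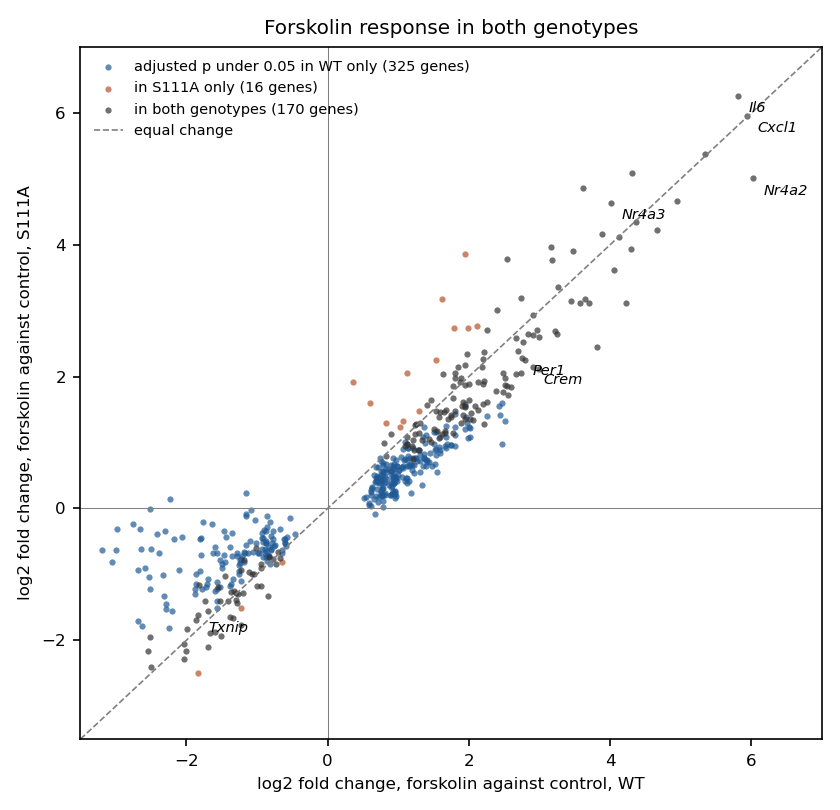
Log2 fold change after forskolin in WT (horizontal axis) and S111A cells (vertical axis) for the 511 genes with a symbol and an adjusted p under 0.05 in either genotype. Each point is 1 gene; 170 passed in both genotypes, 325 in WT alone and 16 in S111A alone, and the genes that passed in both lie near the dashed line of equal change.

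Radiation against control asks which genes respond to DNA damage 120 min after 20 Gy. In WT cells 6 genes rose, among them the p53 targets Btg2 (1.46 ± 0.29 on the log2 scale, SE, 6 arrays against 6) and Mdm2, the ubiquitin ligase for p53 (1.28 ± 0.25), and also Inka2 (1.55 ± 0.25), the AP-1 subunit Fosl1 (1.52 ± 0.29), Mab21l3 (1.34 ± 0.28) and the kinase Dyrk3 (1.25 ± 0.25). Another probe of Mab21l3 had the opposite sign (-1.80, adjusted p = 0.154), and the mean over its probes was -0.23. Inka2 had an adjusted p of 0.00614 and the others of 0.0477, and each was higher on every slide that held both groups (3, and 2 for Dyrk3). Of the lower genes, the rule named Gm2545 (-1.15 ± 0.24), whose sign turned under quantile normalization (0.54) and in the authors' values (0.63) and whose adjusted p was 0.217 with the slide as a block. Of 35 p53 targets 2 rose (21 adjusted over the list alone), with a median of 0.75; Ddit4l (1.58 ± 0.34), Pmaip1 (1.48 ± 0.37) and the cell cycle inhibitor Cdkn1a (1.44 ± 0.43) had adjusted p of 0.0511, 0.0601 and 0.0677 and were higher on 3 of 3 slides. The p53 list passed camera (adjusted p = 3.48e-13) but had adjusted p = 0.175 with an estimated correlation. The cAMP/CREB list held 1 riser, Btg2, of 36 (5 higher and 1 lower adjusted over the list alone; median 0.47; adjusted p = 0.708 with an estimated correlation).

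Limma called 15 genes after radiation in WT cells, 6 higher and 9 lower, while 11195 of 30290 had an unadjusted p under 0.05. With the slide as a block 1 gene, Inka2, remained (adjusted p = 0.0432), and without slide 3 there were 6 genes, all higher, 4 of them shared with the first fit. The split turned with the processing: 2627 of 2913 called genes were higher with normexp, 3172 of 3541 were lower with no filter, and quantile normalization called 0. Within batch A the count was 0 and within batch B it was 2, with changes in batches A and B of 1.73 and 1.37 for Inka2 and 1.55 and 1.01 for Mdm2. The count was 6997, 1 and 11377 without WT control replicate 1, 2 or 3 and 0, 2 and 2 without IR replicate 1, 2 or 3.

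In S111A cells limma called 0 genes after radiation, with 105 at an unadjusted p under 0.05. The p53 targets Btg2 (1.39 ± 0.29 on the log2 scale, SE; adjusted p = 0.196), Ddit4l (1.10 ± 0.34), Gdf15 (1.06 ± 0.30) and Trp53inp1, a p53-induced stress protein gene (0.92 ± 0.19; adjusted p = 0.196), were higher on 5 of 5 slides but did not pass. Without slide 3 the call changed for Btg2 (adjusted p = 0.00476) and Trp53inp1 (adjusted p = 0.00163). Neither group has an array on slide 3, so the changes of these genes stayed at 1.39 and 0.92. Only the spread pooled over all groups changed, so the 0 calls depend in part on arrays of other groups. As a list, 7 of 35 p53 targets were higher when adjusted over the list alone (median 0.27), and the list passed camera with the preset (adjusted p = 3.54e-33) and with an estimated correlation (adjusted p = 0.0035). With the slide as a block 3 genes were called and without slide 3 there were 4. The interaction of genotype and radiation called 0 genes (smallest adjusted p = 0.513; 2413 at an unadjusted p under 0.05). For the p53 list its median was -0.38, and camera gave an adjusted p of 0.000115, lost with adjusted p = 0.708 with an estimated correlation. The p53 score was higher by 0.68 in WT and by 0.39 in S111A cells after radiation (n = 3 each). The two-sided exact permutation p was 0.1 in both, the smallest possible (adjusted p = 0.218). The control score was -0.43 ± 0.67 (SD) in WT and -0.29 ± 0.15 in S111A cells. Low WT control values lay on array A2 of slide 3 (-1.469) and array B2 (-0.876). The differences alone therefore do not show a larger response in WT cells.

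**Figure D4:**
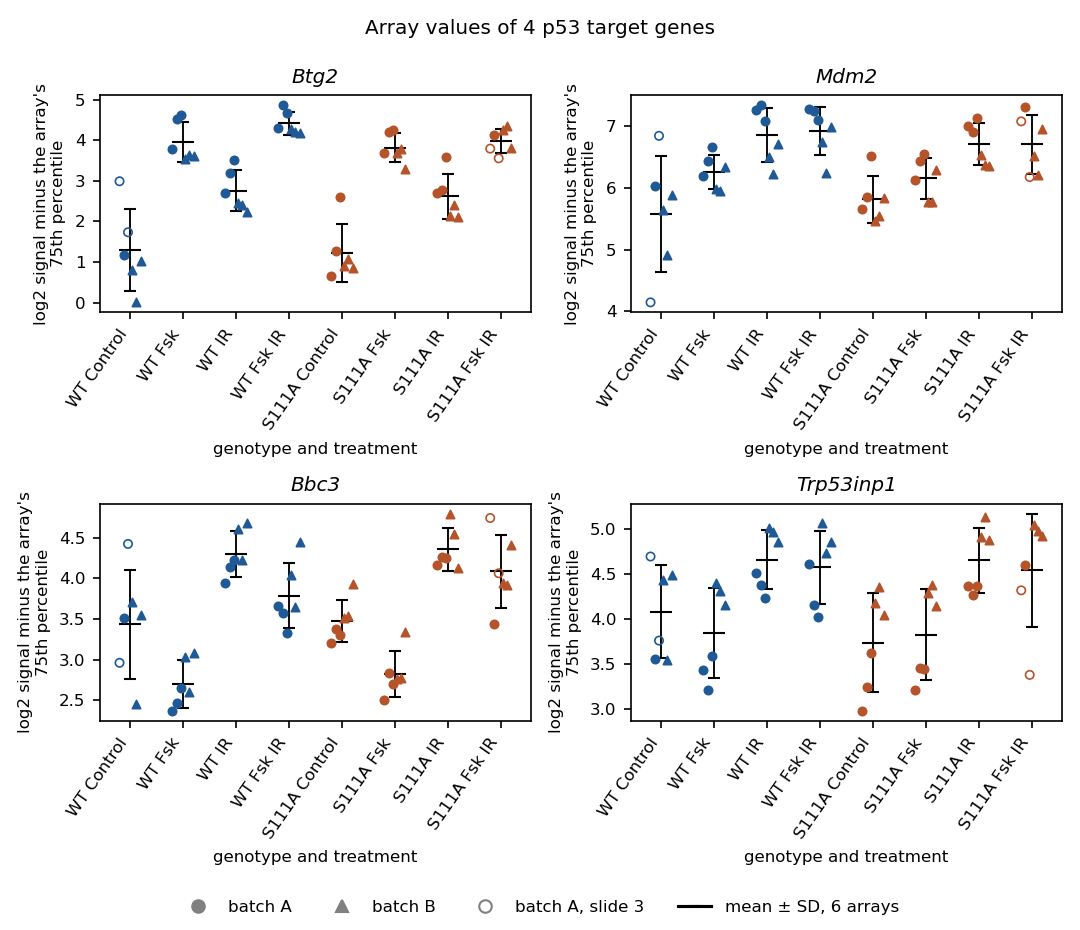
Log2 signal of the p53 targets Btg2, Mdm2, Bbc3 and Trp53inp1 relative to each array's 75th percentile (vertical axis) in the 8 groups of 6 arrays (horizontal axis). Symbols and bars are batch A (circles), batch B (triangles), slide 3 (open circles) and the mean ± SD; mean Bbc3 was 2.82 in S111A Fsk cells and 4.09 in S111A Fsk_IR cells.

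Cells given radiation and then forskolin were compared with control to ask how the treatments act together. In WT cells Cxcl1 rose by 5.78 ± 0.34 on the log2 scale (SE; adjusted p = 1.17e-15), Nr4a2 by 5.59 ± 0.36, Il6 by 5.27 ± 0.59, Fos by 4.68 ± 0.53, Rgs2 by 4.59 ± 0.28, Ier3 by 3.95 ± 0.40, Has1 by 3.76 ± 0.45 and Kcne4 by 3.70 ± 0.27. C2cd4b (5.06 ± 0.70) and Rasd1 (4.09 ± 0.61) rose as well. Nr4a3, above background on 0 of 6 control arrays, rose at least 4.13-fold. Of 35 p53 targets 6 rose (19 higher and 1 lower adjusted over the list alone; adjusted p = 0.175 with an estimated correlation), led by Btg2 (3.13 ± 0.29), Pmaip1 (2.20 ± 0.37), Gdf15 (2.13 ± 0.30) and Plk3 (1.90 ± 0.33). The cAMP/CREB list had 26 risers of 36 (32 higher and 1 lower adjusted over the list alone; median 2.12; adjusted p = 9.56e-06 with an estimated correlation). The growth factor and MAPK list had 9 of 24 (14 adjusted over the list alone; adjusted p = 0.00449 with an estimated correlation), with Vegfa at 2.24 ± 0.32 and Phlda1 at 2.06 ± 0.25. The clock genes Nfil3 (2.58 ± 0.36), Per1 (2.37 ± 0.28) and Bhlhe40 (1.97 ± 0.28) rose, 3 of 21 (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.25 with an estimated correlation). Crem rose by 2.24 ± 0.28. All were higher on every slide with a value for both groups (3, and 2 for Crem).

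Among lower genes after both treatments in WT cells were Txnip (-1.72 ± 0.26, SE; adjusted p = 3.83e-05), Mterf1a, which encodes a mitochondrial transcription termination factor (-1.61 ± 0.19; adjusted p = 1.41e-07), and the NF-kB kinase Map3k14 (-1.15 ± 0.21), each lower on 3 of 3 slides. Less well described transcripts, 9130020K20Rik, BB166591, Sap25, BC023969, D930043N17Rik, 9930012K11Rik and Gm9856, had changes of -2.30 to -1.23. With the slide as a block the calls of Sap25 (adjusted p = 0.099), BC023969 (0.151), D930043N17Rik (0.258) and Gm9856 (0.113; lower on 2 of 3 slides) ended. Limma called 450 genes, 231 higher and 219 lower (5675 at an unadjusted p under 0.05), against 317 with the slide as a block (178 higher, 139 lower). There were 482 without slide 3 (337 higher, 145 lower), with 229 genes in all 3 fits. Quantile normalization gave 276 higher and 73 lower, normexp 595 and 156 and the values deposited by the authors 316 and 77. The count was 1505, 256 and 4042 without WT control replicate 1, 2 or 3, and 238 and 232 without Fsk_IR replicate 1 or 3. Within batch A it was 191 and within batch B 248, and a fit to the 2 compared groups alone called 19.

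In S111A cells the combined treatment raised C2cd4b by 6.20 ± 0.70 on the log2 scale (SE), Il6 by 5.79 ± 0.59, Rasd1 by 5.73 ± 0.61, Cxcl1 by 5.44 ± 0.34 (adjusted p = 5.36e-15), Scrt1 by 5.17 ± 0.42, Nr4a2 by 5.04 ± 0.36, Rgs2 by 4.54 ± 0.28, Has1 by 4.52 ± 0.45, the neurofilament gene Nefl by 4.08 ± 0.54 and Areg by 3.87 ± 0.37. Nr4a3, above background on 0 of 6 control and 4 of 6 treated arrays, rose at least 6.79-fold. Txnip fell by 2.19 ± 0.26 (adjusted p = 2.38e-07), and Lipt1, a lipoyltransferase gene (-2.12 ± 0.30), and the ciliary gene Bbs10 (-2.00 ± 0.25) were lower too. Phxr4, above background on 0 of 6 treated and 6 of 6 control arrays, was at least 1.26-fold lower. Of the 36 cAMP/CREB targets 24 rose (29 higher and 1 lower adjusted over the list alone; adjusted p = 3.18e-07 with an estimated correlation). Of the p53 targets 6 of 35 rose (9 higher and 2 lower adjusted over the list alone; adjusted p = 0.583 with an estimated correlation), led by Btg2 (2.76 ± 0.29), the cytokine Lif (1.93 ± 0.45), Gdf15 (1.91 ± 0.30) and Pmaip1 (1.57 ± 0.37). Inflammatory genes (4 of 25; 7 adjusted over the list alone; adjusted p = 0.000645 with an estimated correlation) included Cxcl2 (3.34 ± 0.66; above background on 1 of 6 control and 4 of 6 treated arrays). Growth factor and MAPK genes (6 of 24; 7 higher and 1 lower adjusted over the list alone; adjusted p = 0.0359 with an estimated correlation) included Vegfa (1.91 ± 0.32). All named genes moved the same way on 3 of 3 slides.

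Limma called 494 genes for both treatments in S111A cells, 183 higher and 311 lower (2638 at an unadjusted p under 0.05), against 772 with the slide as a block (230 higher, 542 lower). There were 708 without slide 3 (341 higher, 367 lower). Quantile normalization gave 183 higher and 185 lower and the values deposited by the authors 204 and 207. The count was 252 and 256 without S111A control replicate 1 or 2, 49 within batch A and 285 within batch B. Between genotypes 127 higher genes and 75 lower genes were shared, against 1.4 and 2.2 if independent, and 707 of the 742 genes called in either had the same sign (95.3%), while over all genes the changes correlated with r = 0.08. The interaction of genotype and the combined treatment called 0 genes with limma (smallest adjusted p = 0.517; 2844 at an unadjusted p under 0.05), and 1 gene without WT control replicate 1.

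Irradiated against unirradiated forskolin-treated cells asks what radiation given 30 min before forskolin adds to forskolin. The labels give no forskolin time or time of collection for the irradiated cells. A difference in these times from the 90 min of the forskolin group is therefore not separated from radiation. Bbc3, which encodes the proapoptotic p53 target PUMA, rose by 1.27 ± 0.22 on the log2 scale (SE; adjusted p = 0.0364) in S111A cells, from 2.82 to 4.09 relative to the array's 75th percentile, higher on 4 of 4 slides. It was the only gene limma called there (1538 at an unadjusted p under 0.05); its change was 1.06 with the slide as a block (adjusted p = 0.0488), and its adjusted p was 0.0565 without slide 3. The count was 0 without S111A Fsk replicate 1, 2 or 3 or Fsk_IR replicate 2 or 3, and 0 within either batch, where the change of Bbc3 was 1.40 (A) and 1.13 (B). In WT cells limma called 0 genes (54 at an unadjusted p under 0.05), and Bbc3 was higher by 1.08 ± 0.22 on 6 of 6 slides without passing (adjusted p = 0.534; 0.0121 with the slide as a block). The p53 targets Ddit4l (1.14 ± 0.34 in WT, 1.06 ± 0.34 in S111A), Sesn2 (0.79 ± 0.27 in both) and Trp53inp1 (0.73 ± 0.19 and 0.72 ± 0.19) were higher on every slide with both groups and did not pass. Without slide 3 Trp53inp1 passed in S111A cells (0.88, adjusted p = 0.0321), the 1 gene called there in that fit. Adjusted over the list alone, 4 of 35 p53 targets were higher in WT and 3 in S111A cells. Camera called the list in WT cells (adjusted p = 1.39e-19; adjusted p = 0.0503 with an estimated correlation). It did not call it in S111A cells (adjusted p = 0.163). The cAMP/CREB list had a median of -0.18 in WT cells (0 of 36 called, also adjusted over the list alone; camera adjusted p = 0.000166, and adjusted p = 0.708 with an estimated correlation). Limma called 0 genes for the interaction of forskolin and radiation in WT (2675 at an unadjusted p under 0.05; smallest adjusted p = 0.331; 3 genes without WT control replicate 1) and 0 in S111A cells (537; 0.931). It called 0 for the interaction of genotype and radiation in forskolin-treated cells (363; 0.986).

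S111A against WT cells at each treatment asks how the genotypes differ. The labels do not say how many embryos or cell lines each genotype came from. A difference between genotypes is therefore not by itself an effect of the substitution. Pam, which encodes an enzyme that amidates peptides (chromosome 1, probe 99718052 to 99718111 on mm9), was higher in S111A cells by 2.04 ± 0.21 on the log2 scale (SE, 6 arrays against 6; adjusted p = 8.7e-08) under control, 1.48 ± 0.21 with forskolin, 1.55 ± 0.21 with radiation and 1.48 ± 0.21 with both, on all 3, 6, 5 and 4 slides with both groups. Gin1, a gene derived from a retroviral integrase (chromosome 1, probe 99674138 to 99674197 on mm9), differed by -1.74 ± 0.30, -1.79 ± 0.30 and -2.17 ± 0.30 with forskolin, radiation and both (adjusted p = 0.00983, 0.00594 and 0.000178), lower on all 6, 5 and 4 slides. Its other probe did not show this, with 0.27, 0.53 and 0.03 (adjusted p = 0.98, 0.992 and 1). Limma called 2 genes in each of the 4 comparisons; the second under control was a chromosome 1 feature known only by an accession. Array weights, chosen after seeing the data, called 1, 5583 (380 higher, 5203 lower), 21 and 18. Unadjusted p under 0.05 occurred for 3591, 1170, 380 and 1239 genes. Under control the count was 224 without WT control replicate 1 and 1 without WT control replicate 3 or S111A control replicate 2. It was 1 with forskolin without any of WT Fsk replicates 1, 2 and 3 or S111A Fsk replicates 1 and 2, and 1 with radiation without WT IR replicate 2 or 3 or S111A IR replicate 2. Within batch A the 4 counts were 0, and within batch B they were 6, 4, 7 and 6; in batches A and B Pam differed by 2.08 and 2.01 under control.

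**Figure D5:**
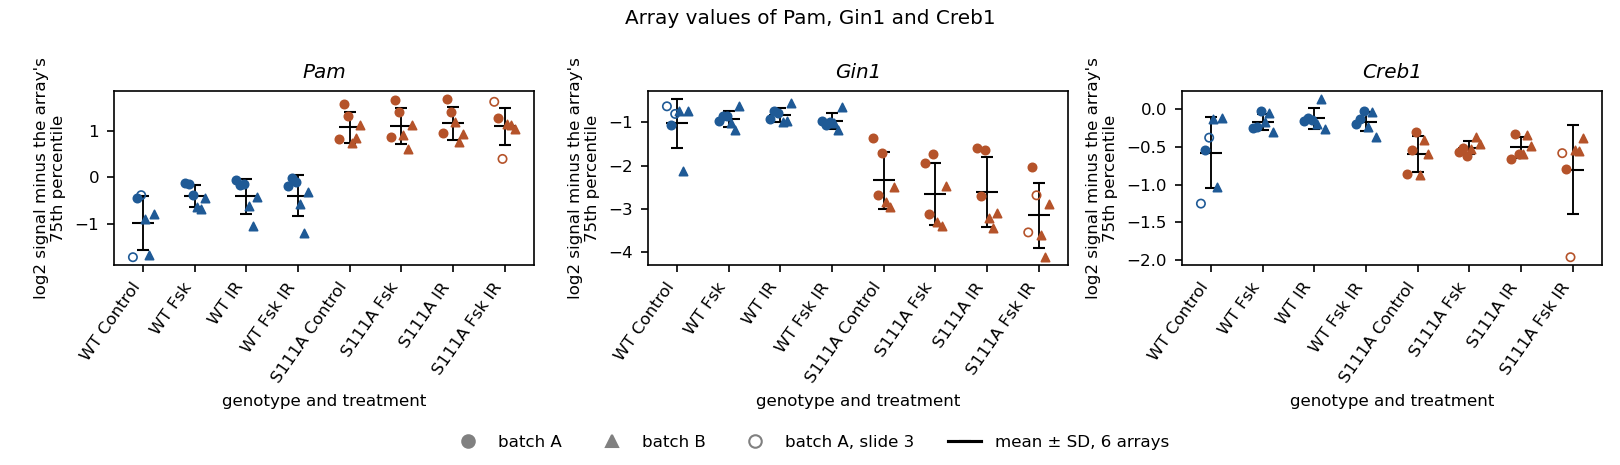
Log2 signal of Pam, Gin1 and Creb1 relative to each array's 75th percentile (vertical axis) in the 8 groups of 6 arrays (horizontal axis). Symbols and bars are batch A (circles), batch B (triangles), slide 3 (open circles) and the mean ± SD; mean Pam under control was -0.97 in WT and 1.07 in S111A cells.

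Creb1 itself, the gene that carries the substitution (chromosome 1, probe 64644633 to 64644692 on mm9), had means of -0.58 ± 0.47 (SD, n = 6) in WT and -0.59 ± 0.23 in S111A controls. Limma called no difference at any treatment: it was -0.02 under control (adjusted p = 0.97), -0.34 with forskolin (0.867), -0.38 with radiation (0.999) and -0.64 with both (1; -0.41 without slide 3). Creb1 was nonetheless lower in S111A cells on 3 of 3, 6 of 6, 5 of 5 and 4 of 4 slides with both genotypes; the WT control mean holds low values on slide 3 (-1.253) and on array B2 (-1.038), and the value with both treatments a low one on slide 3 (-1.966). Averaged over treatments, a contrast added after the data were seen, the difference was -0.34 ± 0.09 (SE, 24 arrays against 24; adjusted p = 0.15). It passed with the slide as a block (-0.35, adjusted p = 0.0413) and without slide 3 (-0.31, adjusted p = 0.0105). The level of the transcript does not check which allele a sample carried. Of the cAMP/CREB targets, Arc, a synaptic immediate early gene, had a difference of -1.07 ± 0.30 (SE) in S111A controls (adjusted p = 0.375; lower on 3 of 3 slides). Its difference was -0.58 ± 0.30 with forskolin (adjusted p = 0.867; lower on 5 of 6 slides), and that of Areg -0.52 ± 0.37 with forskolin (adjusted p = 0.867; lower on 5 of 6 slides). No member of the G2/M list passed, though Aurka (0.76 ± 0.39) and Plk1 (0.75 ± 0.51), mitotic kinases, were higher with forskolin on 6 of 6 slides (adjusted p = 0.867). The median of the G2/M list was 0.57 with forskolin (1.10 in batch A, 0.10 in batch B; adjusted p = 0.549 with an estimated correlation) and 0.29 under control (adjusted p = 0.877 with an estimated correlation). In batches A and B it was 1.03 and -0.10 with radiation and 0.87 and 0.09 with both.

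Markers of other cell types showed no called change as groups that held with an estimated correlation in any of 18 comparisons. The lists for macrophages and leukocytes (15 genes), endothelium (12), neurons and glia (13), fat and blood (9) and embryo sex (6) held 0 called members in limma. Camera called these lists in 3, 1, 0, 2 and 0 of the 18 comparisons, and their smallest adjusted p with an estimated correlation was 0.716, 0.678, 0.708, 0.708 and 0.826. The epithelial list (12 genes) had 1 called member in a single comparison, the tight junction gene Cldn3, which rose by 2.69 ± 0.65 (SE; 3 of 3 slides) in S111A cells after both treatments (adjusted p = 0.0161; 0.0765 with the slide as a block), with a smallest list adjusted p of 0.826 with an estimated correlation.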

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

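The tests of the matrix, cholesterol and contractile lists in S111A cells, of chromosome 1 and of the genotype average, and the fits with the slide as a block or without slide 3, were chosen only after the result was seen. Creb1 was 0.144 on WT_IR array B2, far from the other 5 arrays of its group (nearest -0.108). The cAMP/CREB score was 0.616 on S111A_Fsk array A3 (nearest 0.92). Array A3 of S111A_Fsk_IR, which lies on slide 3, stood apart in 3 measures: Creb1 at -1.97 (nearest -0.795), the cAMP/CREB score at 0.21 (nearest 0.971) and the p53 score at -0.355 (nearest 0.061). These are 5 of 48 tests for an array far from its group, where chance gives about 2.4. No biological explanation was tested for them.

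Matrix, cholesterol synthesis and contractile genes had higher medians in treated than in control WT cells. Over the 3 lists (72 genes) the median after forskolin was 1.30 on the log2 scale in batch A and 0.37 in batch B, 0.42 with the slide as a block and 0.16 without slide 3. A median of 0.08 in S111A cells argues against forskolin raising these genes to a like extent in both genotypes. All genes had a median of -0.13 in that comparison, so a small rise relative to them is not excluded. The high background of slide 3, which holds 2 of the 6 WT control arrays, may account for part of the pattern. It cannot be told apart from another difference of the WT controls, because batch B, with no array on that slide, still gave 0.37. Batch B is not a clean comparison either. Its WT control array B2 had 7015 spots marked as outliers, against 95 to 597 on the other arrays, and an array weight of 0.181.

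Genes that differ between genotypes gathered on chromosome 1, which carries Creb1. Averaged over the 4 treatments (24 arrays against 24), limma called 48 genes, and 29 of the 48 lie there against 5.88% of tested genes (1754 of 29812; Fisher's exact p = 6.48e-24), among them Pam (1.64 ± 0.10, SE), Gin1 (-1.76 ± 0.15), Ptprv (2.65 ± 0.30), Gal3st2 (-2.21 ± 0.26) and Ifi211 (-3.61 ± 0.71). Ptprv, Gal3st2 and Ifi211 were chosen after their values were seen, and with the slide as a block 46 of 164 placed genes and without slide 3 56 of 142 lay on this chromosome. Strain variants linked to the knock-in allele are a candidate explanation. A variant under 1 probe stays open too, since 6 of 41 other probes of these genes (a share of 0.146) differed the same way and passed, and an effect of the substitution itself stays open because these samples do not separate it from linked sequence.

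Zinc finger genes were lower after forskolin in both genotypes. Of 394 genes 78.9% were lower in WT cells (median -0.35, 46 called lower, 2 higher) and 85.5% in S111A cells (median -0.32, 19 lower, 0 higher). Among genes of like signal the shares were 0.52 and 0.608. Fisher's exact tests of the genes called lower, against all 20942 symbols and not matched on signal, gave p = 3.32e-39 and 1.2e-20. They treat these related genes as independent. The median stayed negative under quantile normalization (-0.17 and -0.19), normexp (-0.26 and -0.23) and in the authors' values (-0.16 and -0.20), and relative to all genes it was -0.30 to -0.14 over these scalings. The genes called lower in WT and S111A cells were 26 and 5 under quantile normalization, 67 and 14 with normexp and 27 and 6 in the authors' values. High background of WT control arrays and dim signal are argued against by an excess share of 0.247 in S111A cells without slide 3 and of 0.315 in WT cells with the slide as a block. The S111A share is the same with slide 3, since neither S111A group compared has an array on it. The S111A controls hold an unlike array too, so an effect of it on dim probes is not excluded. On their array A1 the median probe was -2.238 relative to the 75th percentile, against -4.276 to -3.638 on the S111A_Fsk arrays. A fall of zinc finger transcripts with forskolin may be biological, as a hypothesis found and tested on the same data, and after radiation alone the medians were -0.07 and -0.01 (limma called 0).

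Other splits of the arrays within batch, 100 per comparison with the real one included, asked whether chance gives as many genes. For interactions the residuals of the fit without the interaction were shuffled. Chance can be excluded for forskolin in S111A cells (216 genes; 1 split as large; highest other 31) and both treatments in S111A cells (494; 1; 112). For S111A against WT with forskolin (2 genes, 1 split, highest other 1) and radiation (2, 1 and 0) only the real split called as many. Counts this small do not exclude chance by themselves. For both treatments against forskolin in S111A cells (1, 3 and 13) and genotype with both (2, 3 and 112) few splits were as large. With so few genes called they cannot exclude chance. The 1 gene of the former, Bbc3, had a limma adjusted p of 0.0565 without slide 3 and did not pass within either batch. The 2 genes of the latter, Pam and Gin1, were also called with forskolin and radiation, which argues against chance for them. S111A cells with both treatments hold 2 slide 3 arrays. The highest other splits of these 2 comparisons put both arrays in 1 group, so splits that ignore the slide weigh less there. By splits alone chance cannot be excluded for forskolin in WT cells (599; 8; 11174), radiation in WT cells (15; 5; 8850), both treatments in WT cells (450; 9; 12350) or genotype under control (2; 10; 14362). These 4 use the WT controls, and splits that call many times the real count point to a structure of the samples. Each highest split put the 2 slide 3 arrays of the comparison in 1 group, as does the real one. Such structure is not limited to slide 3. For both treatments against forskolin in WT cells, with no array on that slide, the highest other split called 2323 genes. Other values argue against chance for forskolin and for both treatments in WT cells: 402 and 317 genes passed with the slide as a block, and 137 and 127 higher genes were shared with S111A cells against 1.8 and 1.4 if independent. For genotype under control, Pam argues against it too: it differed by 2.04 ± 0.21 (adjusted p = 8.7e-08; 2.64e-06 with the slide as a block and 6.13e-08 without slide 3; 3 of 3 slides) and passed at the 3 other treatments.

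For 8 comparisons limma called 0 genes, so all 100 splits were as large by construction and say nothing about chance. The highest other split was 2323 for both treatments against forskolin in WT, 2 for radiation in S111A, 5263, 5399 and 64 for the interactions of genotype with forskolin, radiation and both, and 0 for genotype with radiation in forskolin-treated cells. It was 959 and 0 for the interaction of forskolin and radiation in WT and S111A cells. The counts at an unadjusted p under 0.05 were 54, 105, 364, 2413, 2844, 363, 2675 and 537.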

How the results depend on the processing

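The fits with the slide as a fixed or random block, without slide 3 and with array weights, and the tests from them, were chosen only after the result was seen. Named genes kept their direction in nearly every setting. For genes named by the rule, which asked for adjusted p under 0.05 and the same sign in both batches, this was partly fixed beforehand. Of 210 pairs of a named gene and comparison, quantile normalization left 174 on their side of the threshold (31 no longer passed), normexp 190, the authors' values 174 and the slide as a fixed block 186 (21 no longer passed). Without slide 3 there were 187, in batch A alone 114 (96 no longer passed) and in batch B alone 170. Among pairs that had passed, directions turned for Gm2545 after radiation in WT cells under quantile normalization (0.54) and in the authors' values (0.63). They also turned for Mab21l3 after radiation in WT cells with the mean over probes (-0.23). Among pairs that had not passed, 1 changed sign in each of the authors' values, batch B alone, without slide 3 and array weights. On leaving out a title number 2 values did so. The pair without slide 3 was Nr4a3 for S111A against WT under control (-0.95 as reported, 0.70 without slide 3). For these and for the counts below, the cause was not tested.

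Counts of genes called by limma are given where they differ from the reported count by more than 1.5 times. Quantile normalization gave 0 for radiation in WT, 1 for both treatments against forskolin in WT, and 5, 1 and 4 for genotype under control, radiation and both. Normexp gave 1974, 2913 and 751 for forskolin, radiation and both in WT, 1 for both against forskolin in WT, 3 for radiation in S111A and 4 for genotype under control. The authors' values gave 2 for radiation in WT, 2 for both against forskolin in WT and in S111A, 3 for radiation in S111A, and 11, 1 and 4 for genotype under control, radiation and both. Without a filter radiation in WT gave 3541. With only probes above background on all 48 arrays, which tests fewer genes, the counts were 261, 2 and 131 for forskolin, radiation and both in WT, 67, 2 and 160 in S111A, and 0 for genotype at each treatment. The mean over probes gave 1303 for radiation in WT and 1 for genotype at each treatment.

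Radiation in WT gave 635 with 48 independent arrays, 2336 with no batch term and 6 with a variance trend. With no batch term genotype gave 4 under control and 4 with both. With the arrays of a title number averaged, which leaves 24 samples, radiation in WT, both against forskolin in S111A, and genotype with forskolin and radiation gave 0, and genotype with both gave 1. Batch A alone, with fewer arrays, gave 230, 0 and 191 in WT, 32 and 49 for forskolin and both in S111A, and 0 for both against forskolin in S111A and for genotype at each treatment. Batch B alone gave 313, 2 and 248 in WT, 285 for both in S111A, 0 for both against forskolin in S111A, and 6, 4, 7 and 6 for genotype. Only the groups compared gave 63, 0 and 19 in WT, 144 for both in S111A, 0 for both against forskolin in S111A, and 0, 1 and 0 for genotype under control, forskolin and both.

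A replicate block, the replicate number within its batch, gave 1216, 5635 and 979 in WT, 345, 4 and 850 in S111A, and 20, 6, 5 and 4 for genotype. Numbers do not pair these samples by their labels, but arrays with 1 number in a batch had a median correlation of 0.327 (105 of 168 pairs above 0.1), and 32 of 48 arrays correlated best with 1 of their own number. Most arrays with 1 number in a batch also share a slide. Arrays of 1 slide had a median correlation of 0.386, and 30 of 48 correlated best with 1 of their own slide. Number and slide are therefore hardly separated here. The block raised the count in each comparison named here.

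The slide as a fixed block gave 1 for radiation and 1 for both against forskolin in WT, 386, 3 and 772 in S111A, 2 for both against forskolin there, and 6 and 4 for genotype with forskolin and radiation. As a random block it gave 7 and 1 in WT, 471, 5, 865 and 2 in S111A, and 8 and 4 for genotype. Without slide 3 the counts were 6 for radiation and 1 for both against forskolin in WT, 478 and 4 for forskolin and radiation in S111A, and 1 and 7 for genotype under control and radiation. Of these, only radiation in WT and genotype under control use groups with slide 3 arrays. For the others only the pooled spread changed. Array weights gave 356, 1 and 227 in WT, 2 for both against forskolin there, 727, 10, 1315 and 3 in S111A, and 1, 5583, 21 and 18 for genotype.

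Leaving out 1 title number gave 264 to 4035, 0 to 11377 and 232 to 4042 genes for forskolin, radiation and both in WT, 138 to 189 and 252 to 654 for forskolin and both in S111A, and 0 to 1 for both against forskolin there. Genotype gave 1 to 224, 1 to 2, 1 to 3 and 2 to 3. The interaction of genotype and both treatments gave 0 to 1 and that of forskolin and radiation in WT 0 to 3. The other comparisons with 0 reported genes gave 0 throughout. The highest counts in WT cells came without WT control replicate 3. Over these settings 1110 values of named genes kept their side of the threshold while 147 no longer passed.

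Camera called 138 of 396 tests of lists, against 11 with an estimated correlation, 16 with fry, 129 with the slide as a fixed block and 131 without slide 3. The cAMP/CREB score after forskolin in WT was 2.37 as reported and 1.65 with z-scored members. Detection limits what the arrays of slide 3 show. These had high negative control signals and 12961 to 25494 probes above background, against 20367 or more on the other slides. A block for the scan date was not run.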

Other observations

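The tests of correlations between arrays of a slide were chosen only after the result was seen. Ppargc1a, which encodes the coactivator PGC-1alpha, rose after forskolin by 2.18 ± 0.51 on the log2 scale (SE, adjusted p = 0.0123, 3 of 3 slides) in WT cells. In S111A cells it rose by 2.15 ± 0.51 (adjusted p = 0.0253, 5 of 5 slides). It was the only called member of 27 genes for gluconeogenesis and PGC-1alpha in both comparisons (1 adjusted over the list alone in each), and the list's adjusted camera p was 0.448 and 0.159. After both treatments Ppargc1a rose by 2.02 ± 0.51 in S111A cells (adjusted p = 0.0259, 3 of 3 slides) and did not pass in WT cells (1.36 ± 0.51, adjusted p = 0.179, 3 of 3 slides), where it passed without slide 3 (1.93, adjusted p = 0.0218). Over the 18 comparisons the list was called by camera in 0.

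Sox9, a transcription factor of cartilage formation, was the only called member of 13 skeletal, cardiac and cartilage genes after forskolin. It rose by 1.51 ± 0.25 on the log2 scale (SE, adjusted p = 0.000164, 3 of 3 slides) in WT and by 1.20 ± 0.25 (adjusted p = 0.00641, 5 of 5 slides) in S111A cells. After both treatments it rose by 1.28 ± 0.25 and 1.12 ± 0.25 (adjusted p = 0.00234 and 0.00955, 3 of 3 slides in each). The list passed camera after both treatments in S111A cells (adjusted p = 0.000187; 2 genes adjusted over the list alone), with adjusted p = 0.0675 with an estimated correlation.

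Oxidative phosphorylation genes held 0 called members of 26 in limma after forskolin in WT cells, with a median of 0.21 (0 adjusted over the list alone; adjusted p = 0.826 with an estimated correlation). Of 23 cholesterol synthesis genes 0 passed, with a median of 0.54 (0 adjusted over the list alone; adjusted p = 0.758 with an estimated correlation). That median was 0.79 in batch A, 0.34 in batch B, 0.32 with the slide as a block and 0.10 without slide 3. Forskolin in WT cells had 5487 genes at an unadjusted p under 0.05.

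The first component of variation between arrays held 50.2% of the variance, 43.4% of it between slides and 21.3% between groups. The second held 13.1%, with 86.5% of it between batches. On the first component the slide 3 arrays had values of 168.2 to 308.9. Arrays of other slides lay in this range too: WT control B1 (185.1) and B2 (174.3), S111A control A1 (225.1) and WT Fsk_IR B2 (198.2). Leaving out slide 3 therefore does not remove every array of this kind. After removal of group and batch means, arrays of 1 title number had a median correlation of -0.16 (6 of 24 pairs above 0.1) and arrays of 1 slide 0.386 (87 of 131). For other probes of the named genes 27 values were found, of which 23 had the sign of the named probe (17 passing) and 4 the opposite sign (0 passing), 3 of them for Gin1 and 1 for Mab21l3.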
